A study of Homo sapiens with 21 samples.

How the data were processed

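Polyadenylated RNA was sequenced in 21 libraries, in 7 groups of 3. In the first experiment, primary human keratinocytes were kept for 48 h in conditioned medium (CM), that is, medium taken from other cells: from 1341D melanoma cells, from 501mel melanoma cells or from normal melanocytes. In the second, the melanoma lines WM1341D and 501mel were kept for 24 h in CM from keratinocytes carrying a short hairpin RNA against desmoglein 1 (shDsg1) or a non-targeting one (shNT). The numbers 1 to 3 in the labels were read as replicate numbers. The series record speaks of keratinocyte clonal variation, but it does not say what a replicate number stands for or whether replicates were separate cultures or donors, so p-values measure only the spread between these samples.

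The deposited table holds FPKM values (fragments scaled by gene length and library size) made by the authors for 58735 genes, with 1 column per library and a gene length in bases. The submitters' processing notes give HISAT2 2.0.5 and genome build hg38; the read counter, the FPKM formula and the strand setting are not stated in the records used here. According to the series record, the authors tested genes with DESeq2 and a batch correction for keratinocyte clonal variation, at an unadjusted p under 0.05 and an absolute log2 fold change above 1. Every FPKM value times gene length was a whole multiple of 1 step per library (100% of values within 0.01), so whole reads could be recovered. Each library held from 12710 to 16186 genes above the minimum. The scale of the FPKM values matched median-of-ratios size factors over the 21 libraries, not plain totals, and the scale divided by the plain total ran from 0.696 to 1.33.

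The comparisons, gene lists, tests and rules below were fixed before the data were examined. Because the table held FPKM and not counts, the planned count models (edgeR as the main test, and DESeq2 at both thresholds) were not used, nor were their alternatives of TMM scaling and count filters. The test fixed for that case was used: limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(FPKM + 1), over genes with a mean of at least 0.5 FPKM in the libraries of the fit. That left 15011 genes in the 9 keratinocyte libraries and 13798 in the 12 melanoma cell libraries. A gene near 0 in 1 melanoma line but not in the other can therefore count as tested in both. Keratinocyte fits had medium and replicate number as terms. Melanoma cell fits had a block for each line and replicate number, with the shDsg1 effect within each line and their difference. The comparison of the 2 lines had group means only. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and counts at the authors' threshold are given beside them. A log2 fold change is a difference of mean log2(FPKM + 1), so it understates folds of genes near 0.

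Same-numbered libraries were checked for pairing by the correlation, across genes, of their deviations from the group mean. All 15 such pairs exceeded 0.1, with r from 0.131 to 0.827 in keratinocytes, 0.603 to 0.660 in WM1341D and 0.369 to 0.676 in 501mel cells. The fits were tested on simulated data in which 100 genes were given a 2-fold and 100 a 4-fold change. At 2-fold, 88% were recovered for 501mel CM against melanocyte CM, 99% for shDsg1 in WM1341D cells, 98% for the difference between lines and 93% between the lines. Of the genes left unchanged, 17, 6, 9 and 14 were called. Changes were given only to genes with a mean log2(FPKM + 1) above 2. The noise was drawn independently for each gene and library, without deviations shared across genes or the likeness between keratinocyte replicates described below. The simulation therefore cannot say how many real changes of this size the tests missed.

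Gene groups were tested with 26 lists of genes fixed from textbook knowledge, 24 of them for keratinocytes and 23 for melanoma cells. The camera test was run with a preset correlation of 0.01, adjusted over the lists of a comparison with at least 5 tested members, and again with an estimated correlation. The fry test was run as an alternative; it asks whether the genes of a list move, on balance, in 1 direction, and compares no list with other genes. Counts of list members are given over all genes tested and adjusted over the list alone.

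Named genes follow a fixed rule. In each comparison these are up to 10 called genes per direction, or, where none was called, the 3 highest and the 3 lowest test statistics among protein coding genes of at least 1 FPKM. DSG1, SNAI2, CXCL1 and CXCL8 were always named, and so were up to 4 members of each list with the smallest p. Errors are SD over 3 libraries for FPKM and SE for log2 fold changes.

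The alternatives tried were a pseudocount of 0.1, no filter on low values, no replicate block, a block common to both lines, the compared libraries alone, leaving out each library in turn, and the authors' and a stricter threshold. After the data were seen, others were added: limma's voom on the recovered reads, protein coding genes of at least 1 FPKM, every gene kept, FPKM rescaled to plain read totals, and keratinocyte replicates taken by pairs. Voom also scaled by plain read totals, so it and the rescaled FPKM are not separate checks of the scaling. Each library was also fitted as a non-negative sum of the other libraries of its group, over genes with at least 600 reads in those 3 libraries. Shares of mitochondrial reads had 95% Wilson intervals at most 0.0278 points wide; these cover counting error only, since reads without molecular identifiers are not independent molecules. No library and no column was left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.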

Results

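The data are 9 keratinocyte libraries (3 per medium) and 12 melanoma cell libraries (3 per line and medium), with 12710 to 16186 genes above the minimum and 15.0 to 23.1 Mreads (1e6 reads) recovered in each. Replicate 1 of the keratinocytes stood apart in every medium. Its mitochondrial read share was 6.06% to 7.36%, against 1.26% to 1.32% in replicate 2 and 2.68% to 3.59% in replicate 3. It was also lower in differentiation genes, with a list median of 52.9 to 61.8 FPKM against 147 to 212 in replicate 2 and 129 to 164 in replicate 3, and in DSG1, at 4.79 to 8.10 against 12.1 to 45.9 and 8.09 to 33.1. Transcripts of fibroblasts moved with it: the collagen genes COL1A2 and COL1A1, chosen after their values were seen, had 7.05 to 8.81 and 28.2 to 37.6 FPKM in replicate 1, 0.0769 to 0.142 and 1.49 to 4.96 in replicate 2 and 2.01 to 4.30 and 10.1 to 17.7 in replicate 3. For most genes replicate 3 lay between the other 2. Of the genes at least 4-fold different between replicates 1 and 2, the value of replicate 3 lay between theirs for 641 of 641 in 1341D CM, 971 of 972 in 501mel CM and 488 of 489 in melanocyte CM. The same choice of genes, which favours a value between, gave 50% to 81.6% in the melanoma cell groups, over 9 to 38 genes. Over all genes with enough reads this held for 80.5% to 82.6% in keratinocytes and 21.6% to 40.8% in melanoma cells, where chance gives 33.3%. Fitted as a sum of replicates 1 and 2 of the same medium, replicate 3 took 24.6%, 42.9% and 23.3% from replicate 1 in 1341D, 501mel and melanocyte CM. Its median absolute log2 residual was 0.0591 to 0.0885, against 0.129 to 0.235 in the 12 melanoma cell fits. The tests treat the 3 keratinocyte replicates as independent. Every adjusted p, count of calls and count of pairs in the same direction below for keratinocytes is to be read with this limit. It weighs most where replicates 2 and 3 are taken alone. Replicate 2 made up 75.4%, 57.1% and 76.7% of the fit of replicate 3 in 1341D, 501mel and melanocyte CM.

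**Figure D1:**
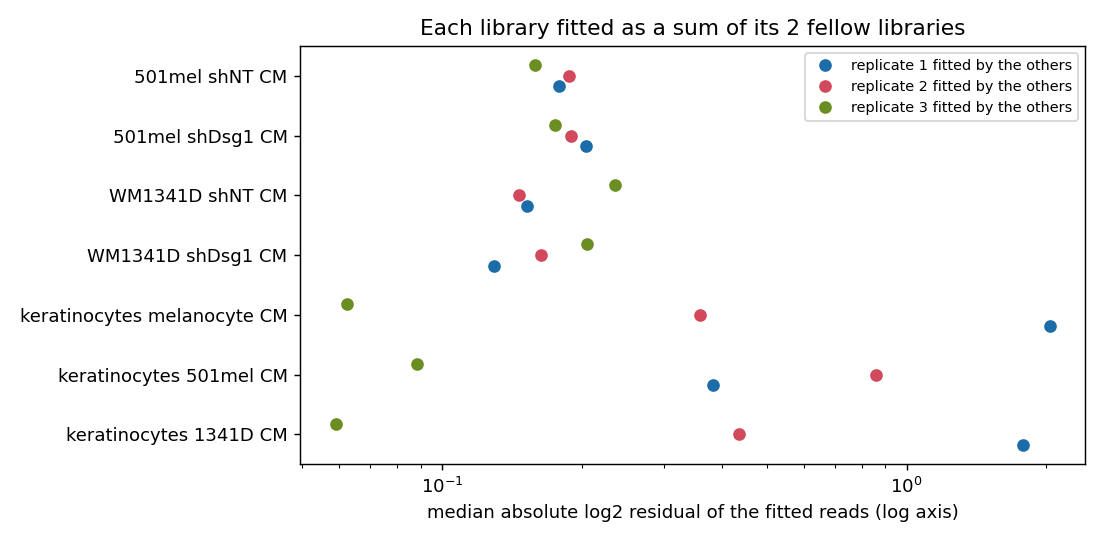
Median absolute log2 residual (log axis) of each library fitted as a sum of the 2 other libraries of its group, 1 point per library. Keratinocyte replicate 3 lies at 0.0591 to 0.0885 in the 3 media, below all 12 melanoma cell libraries (0.129 to 0.235), and keratinocyte replicates 1 and 2 lie at 0.359 or above.

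The study's title names desmoglein 1 in keratinocytes, and the first comparison asks which keratinocyte genes differ between CM of 1341D melanoma cells and CM of melanocytes. DSG1 (ENSG00000134760, chromosome 18, 31318089 to 31357029), a desmosomal cadherin of the upper epidermis, measured 28.2 FPKM ± 20.5 (SD, n = 3) in 1341D CM and 23.0 ± 13.4 in melanocyte CM. Its log2 fold change was 0.09 (SE 0.31, adjusted p = 0.924), and its direction turned without 1341D CM replicate 2 (-0.13) or replicate 3 (-0.11). CA9, a carbonic anhydrase of the cell surface induced by low oxygen, was at 0.655 ± 0.234 against 4.21 ± 0.799 FPKM, a log2 fold change of -1.65 (SE 0.14, adjusted p = 0.149) and lower in 3 of 3 pairs. In 17 alternative fits CA9 ran from -2.82 to -1.56 and passed in 3 (lowest adjusted p 0.0189). NDUFA4L2, another gene induced by low oxygen, had 3.96 ± 2.85 against 13.0 ± 6.08 FPKM, and the transcription factor MAF 2.75 ± 0.44 against 6.03 ± 0.31. The highest statistics were those of CYP1A1, a target of the aryl hydrocarbon receptor (3.36 ± 0.32 against 1.26 ± 0.39 FPKM), RPTN, a cornified envelope protein (2.23 ± 0.38 against 0.763 ± 0.126) and GGT6 (31 ± 20.2 against 17.1 ± 11.8). SNAI2, a transcription factor of epithelial-mesenchymal transition, and the neutrophil chemokines CXCL1 and CXCL8 had log2 fold changes of 0.07, 0.39 and -0.02 (adjusted p = 0.841, 0.585 and 0.980).

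Among gene groups, 30 of 32 interferon response genes had lower values in 1341D CM, with a list median of -0.49 (adjusted p = 8.0e-06; adjusted p = 0.669 with an estimated correlation). IFI44L measured 4.68 ± 0.83 against 9.96 ± 0.41 FPKM and STAT2, which carries the interferon signal to the nucleus, 9.68 ± 4.92 against 15.3 ± 4.81. OASL went the other way at 35.8 ± 27.0 against 12.5 ± 5.68. The integrated stress response list had 21 of 23 members higher and a median of 0.34 (adjusted p = 7.7e-05; adjusted p = 0.669 with an estimated correlation); CHAC1, which degrades glutathione, stood at 173 ± 117 against 86.0 ± 63.7 FPKM and STC2, a secreted glycoprotein, at 59.4 ± 48.2 against 39.0 ± 31.8. ERK pathway and immediate early genes had a median of 0.30 with 19 of 25 higher (adjusted p = 0.000474; adjusted p = 0.669 with an estimated correlation). EGR3 was at 40.3 ± 31.7 against 11.9 ± 5.91 and the growth factor AREG at 454 ± 165 against 326 ± 89.5. JUN was at 97.1 ± 11.8 against 129 ± 15.5. Cell cycle genes had a median of -0.23 with 21 of 29 lower (adjusted p = 0.000474; adjusted p = 0.622 with an estimated correlation). The proliferation marker MKI67 was at 1.35 ± 0.42 against 2.28 ± 0.79. The hypoxia list, with NDRG1 at 68.6 ± 37.9 against 147 ± 88.9 FPKM, had 16 of 24 members lower and a median of -0.17 (adjusted p = 0.00204; adjusted p = 0.669 with an estimated correlation). All 5 metallothioneins tested, proteins that bind zinc and copper, were higher, MT1X at 46.9 ± 23.4 against 32.8 ± 16.0 (list median 0.37, adjusted p = 0.0106; adjusted p = 0.622 with an estimated correlation), though by pair their medians were -0.09, 0.75 and 0.34. With these groups, the 13 mitochondrially encoded genes, kept as a sign of RNA quality, were all higher. Their median was 0.21 (adjusted p = 0.00837, and 0.669 with an estimated correlation). Their share of reads, from melanocyte to 1341D CM, rose in pair 1 (6.06% to 7.36%) and pair 3 (2.68% to 3.00%). In pair 2 it fell from 1.32% to 1.26%. Among genes of differentiation, CASP14, the protease of the cornified layer, had 53.3 ± 20.2 against 107 ± 48.6 FPKM and IVL, a cornified envelope protein, 424 ± 182 against 591 ± 278, but 22 of 39 list members were higher and the list was not called (adjusted p = 0.528). The collagenase MMP1 had 9.88 ± 5.79 against 31.3 ± 19.1 FPKM.

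None of the 15011 genes passed the limma test. Of all genes, 1694 had an unadjusted p under 0.05 where 751 would by chance, voom called 0, and 184 met the authors' threshold, 124 higher and 60 lower. This balance rested on the replicates kept: 34 were higher and 45 lower with replicates 1 and 2 alone, 59 and 85 with 1 and 3, and 431 and 129 with 2 and 3. Adjusted over the list alone, genes passed in 7 lists: 2 metallothioneins higher, 2 hypoxia and 2 differentiation genes lower, 1 chemokine gene lower, 1 oxidative stress gene higher, 1 Notch gene lower and 4 protease genes (3 lower). Without melanocyte CM replicate 1, 887 genes were called, and with replicates 2 and 3 alone 633. The 16 lists not called had medians from -0.20 to 0.16 (adjusted p = 0.0625 to 0.953). For the desmosome, epithelial-mesenchymal transition and chemokine lists the median, mean and test differed in sign. By pair the ERK medians were 0.05, 0.55 and 0.39. With 1 library left out, list medians ran from -0.79 to -0.23 for interferon, 0.17 to 0.50 for ERK, 0.23 to 0.47 for stress response, -0.33 to -0.15 for cell cycle, -0.15 to -0.08 for hypoxia, 0.11 to 0.53 for metallothionein and 0.13 to 0.28 for mitochondrially encoded genes. Leaving out 1 library ended the call of metallothioneins (melanocyte CM replicate 2, adjusted p = 0.0958), of hypoxia (melanocyte CM replicate 1, adjusted p = 0.204) and of mitochondrially encoded genes (1341D CM replicate 1, adjusted p = 0.144; melanocyte CM replicate 3, adjusted p = 0.192).

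**Figure D2:**
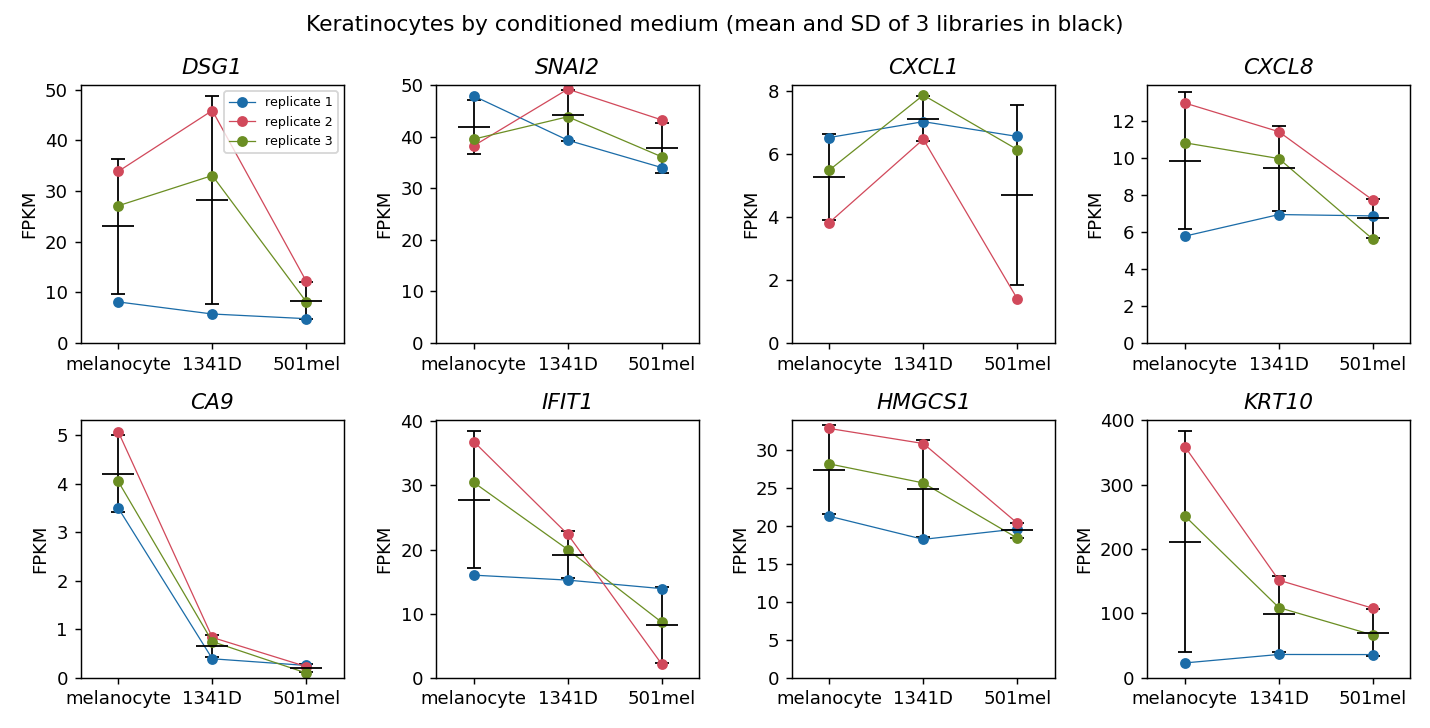
FPKM of 8 genes in keratinocytes in CM of melanocytes, 1341D and 501mel cells, 1 point per library, with lines joining same-numbered replicates and the mean and SD of 3 libraries in black. DSG1 means are 23.0, 28.2 and 8.34 FPKM and CA9 means 4.21, 0.655 and 0.192 FPKM.

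The second comparison puts CM of 501mel melanoma cells against CM of melanocytes. CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159) was the gene called: it measured 0.192 ± 0.084 FPKM (SD, n = 3) against 4.21 ± 0.80 and fell by 2.12 on the log2 scale (SE 0.14, adjusted p = 0.0298), lower in 3 of 3 pairs. DSG1 measured 8.34 ± 3.68 against 23.0 ± 13.4 FPKM, a log2 fold change of -1.23 (SE 0.31, adjusted p = 0.20) that was negative in 3 of 3 pairs and did not pass. It passed without 501mel CM replicate 1 (log2 fold change -1.65, adjusted p = 0.0191) and with replicates 2 and 3 alone (-1.52, adjusted p = 0.00338). Those 2 replicates may not be independent: replicate 3 was fitted as 57.1% (501mel CM) and 76.7% (melanocyte CM) replicate 2. CASP14 had 24.3 ± 6.58 against 107 ± 48.6 FPKM (log2 fold change -1.99, adjusted p = 0.088), and FLG, the filaggrin gene of the granular layer, 7.82 ± 5.19 against 25.4 ± 19.0. SNAI2, CXCL1 and CXCL8 had log2 fold changes of -0.15, -0.29 and -0.43 (adjusted p = 0.572, 0.577 and 0.264).

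Interferon response genes had the lowest values as a group: 31 of 32 were lower in 501mel CM, with a median of -1.13 (adjusted p = 5.9e-13; adjusted p = 0.634 with an estimated correlation). Adjusted over the list alone, 28 were lower and 1 higher. IRF7, the transcription factor that drives interferon genes, stood at 42.8 ± 11.8 against 86.9 ± 13.1 FPKM, the antiviral enzyme OAS3 at 25 ± 5.84 against 53.2 ± 25.9 and IFI44L at 3.87 ± 2.18 against 9.96 ± 0.41. The list median was -0.15 in pair 1, -1.95 in pair 2 and -1.16 in pair 3. Genes of cholesterol synthesis followed with 18 of 22 lower and a median of -0.58 (adjusted p = 4.2e-05; adjusted p = 0.634 with an estimated correlation), and their medians by pair were 0.05, -1.12 and -0.66. SQLE, an oxygen-dependent enzyme of the pathway, measured 41.4 ± 1.41 against 74.9 ± 27.8 FPKM and STARD4, a carrier of cholesterol, 6.63 ± 2.86 against 13.4 ± 1.19. In the desmosome and cadherin list 13 of 17 members were lower, with a median of -0.20 and medians by pair of 0.04, -0.39 and -0.35 (adjusted p = 0.0246; adjusted p = 0.635 with an estimated correlation). Beside DSG1, the desmocollin DSC1 had 1.70 ± 1.01 against 9.75 ± 8.21 FPKM and CTNND1, the p120 catenin gene, 32.5 ± 8.57 against 53.7 ± 12.7. Hypoxia genes were lower in 16 of 24 cases, with a median of -0.23 (adjusted p = 0.00159; adjusted p = 0.634 with an estimated correlation), NDRG1 at 67.1 ± 42.4 against 147 ± 88.9.

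The list of wound and activation keratins, which also holds keratins of simple epithelia, had higher values in 8 of 9 cases. None passed alone, and the median was 0.33 (adjusted p = 0.0194, and 0.634 with an estimated correlation). KRT7 stood at 196 ± 5.97 against 103 ± 68.0 FPKM and KRT19, both keratins of simple epithelia, at 500 ± 414 against 324 ± 341. ERK pathway genes had 20 of 25 higher and a median of 0.25 (adjusted p = 0.0179; adjusted p = 0.635 with an estimated correlation), with the growth factor HBEGF at 81.4 ± 68.6 against 39.8 ± 25.5. EGR1 and JUN were at 66.6 ± 11.9 against 125 ± 57.2 and at 93.1 ± 11.9 against 129 ± 15.5. The 13 mitochondrially encoded genes were again all higher (median 0.35, adjusted p = 0.000233, and 0.634 with an estimated correlation). Their share of reads, from melanocyte to 501mel CM, rose in pair 1 (6.06% to 6.68%) and pair 3 (2.68% to 3.59%). In pair 2 it fell from 1.32% to 1.28%, so the rise there depends on the scaling of the FPKM. The differentiation list went both ways: adjusted over the list alone 12 members were higher and 7 lower, and the list was not called (adjusted p = 0.412). HMOX1, the heme oxygenase induced by oxidative stress, measured 158 ± 152 against 18.1 ± 11.3 FPKM, and the stromelysin MMP3 0.427 ± 0.039 against 9.52 ± 7.30; adjusted over the list alone 1 oxidative stress gene was higher, 4 protease genes were higher and 5 lower, and 1 chemokine gene was higher and 1 lower. Lower by the same measure were 3 hypoxia genes, 1 ERK gene and 1 Notch gene.

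Of 15011 genes, 3182 had an unadjusted p under 0.05 (751 by chance) and 508 met the authors' threshold, 361 higher and 147 lower. With replicates 1 and 2 alone 58 were higher and 60 lower, with 1 and 3 alone 71 and 75, and with 2 and 3 alone 853 and 411. The voom test called 3, CA9, CASP14 and NDUFA4L2, the last chosen after its values were seen. The CA9 call was lost without 501mel CM replicate 2 or 3 or melanocyte CM replicate 2 or 3 (0 genes each, adjusted p of CA9 0.310, 0.484, 0.330 and 0.451), while its log2 fold change stayed between -2.27 and -2.05 with any library left out. By contrast, 1492 genes were called without 501mel CM replicate 1, 2528 without melanocyte CM replicate 1 and 3404 with replicates 2 and 3 alone. Calls of lists ended without 1 library for desmosome genes (501mel CM replicate 2 or 3, adjusted p = 0.0766 and 0.132; melanocyte CM replicate 1, 0.0698) and ERK genes (501mel CM replicate 2, 0.0739; melanocyte CM replicate 2, 0.111). The same held for wound keratins (501mel CM replicate 1, 0.0775; melanocyte CM replicate 2, 0.0671) and hypoxia (501mel CM replicate 1, 0.0904; melanocyte CM replicate 1, 0.124). With 1 library left out, list medians ran from -1.53 to -0.74 for interferon, -0.88 to -0.34 for cholesterol synthesis, -0.37 to -0.12 for desmosome, 0.11 to 0.40 for ERK, -0.27 to -0.21 for hypoxia and 0.26 to 0.47 for mitochondrially encoded genes, and 0.25 to 0.43 for wound keratins. The 16 lists not called had medians from -0.27 to 0.23 (adjusted p = 0.0955 to 0.911). Median, mean and test differed in sign for the epithelial-mesenchymal transition, TGF-beta and cell cycle lists.

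**Figure D3:**
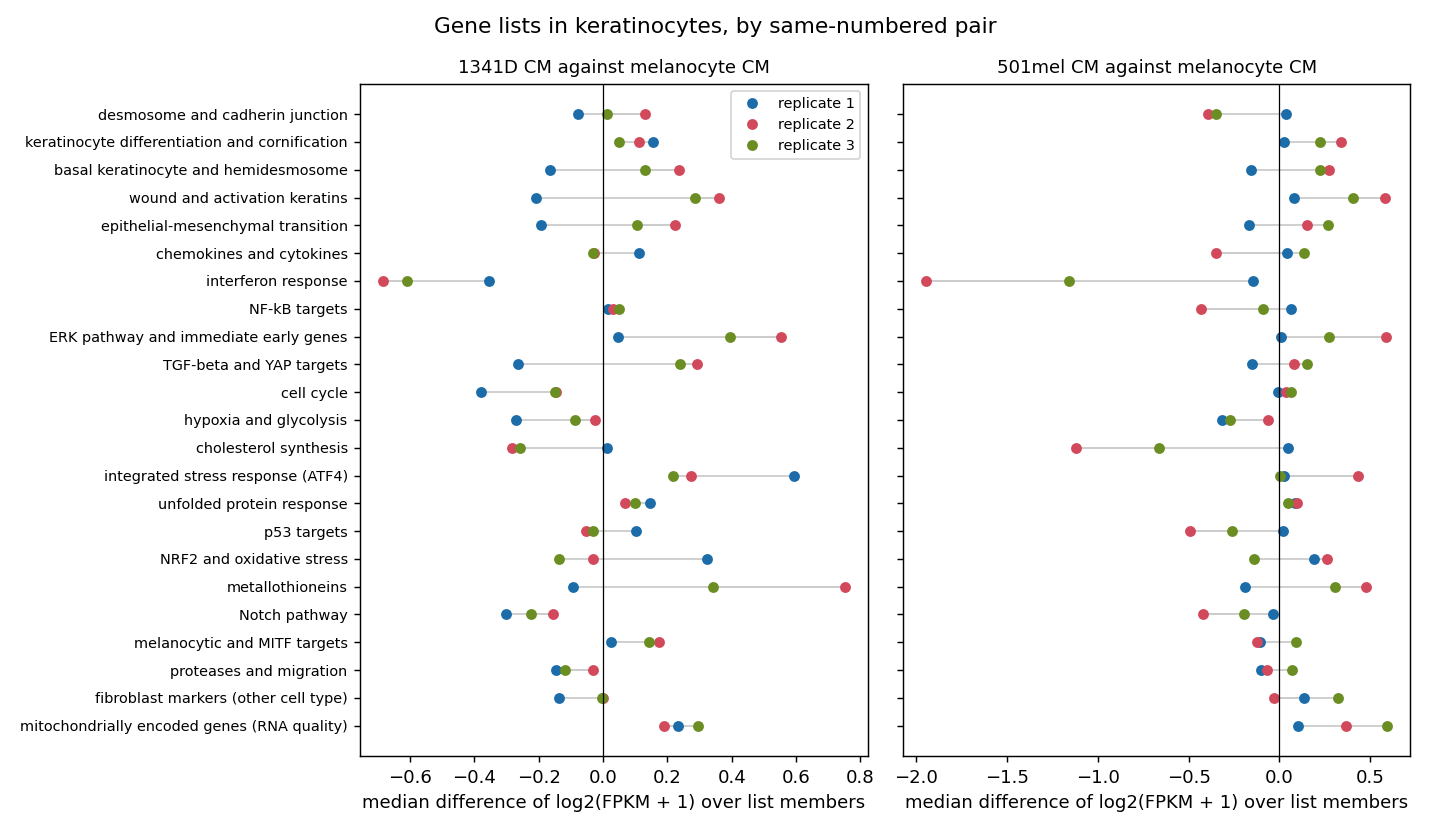
Median difference of log2(FPKM + 1) over the members of each gene list with at least 5 tested members, in 1341D CM (left) and 501mel CM (right) against melanocyte CM, 1 point per same-numbered pair. Interferon response genes lie at -0.36, -0.68 and -0.61 on the left and at -0.15, -1.95 and -1.16 on the right for pairs 1, 2 and 3.

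Both media of melanoma cells were compared with the same 3 melanocyte CM libraries, which cannot be split into parts of at least 2. At the adjusted threshold no gene was called in both. At the authors' threshold 121 genes were in both lists, 80 higher and 41 lower, where independent lists would share 2.98 and 0.588 and simulated data with shared controls and no effect shared 8.24 on average (2 to 14). The correlation of log2 fold changes across genes, which are not independent replicates, was 0.775 against a simulated 0.502, and the covariance 0.115 against 0.0221. Part of the excess in shared genes may come from the shared controls. The simulated noise was independent between genes and libraries. It lacked deviations shared across genes and the likeness between keratinocyte replicates, so the simulated ranges may be too narrow. The excess over them is therefore no measure of a shared effect of the media.

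The third comparison sets the 2 melanoma media against each other in keratinocytes. DSG1 had 8.34 ± 3.68 FPKM (SD, n = 3) in 501mel CM and 28.2 ± 20.5 in 1341D CM, a log2 fold change of -1.32 (SE 0.31, adjusted p = 0.667) with 3 of 3 pairs negative. ALOX12B, a lipoxygenase of the skin barrier, measured 15.0 ± 12.5 against 36.8 ± 29.2 FPKM, CASP14 24.3 ± 6.58 against 53.3 ± 20.2 and ZSCAN4 1.65 ± 0.23 against 3.47 ± 0.62. NMU, a neuropeptide, had 2.18 ± 0.51 against 0.889 ± 0.345 FPKM, LHB 3.22 ± 2.85 against 1.12 ± 1.51 and FAM167B 4.36 ± 3.10 against 2.48 ± 2.07. The collagenase MMP1 stood at 35.4 ± 30.4 against 9.88 ± 5.79 FPKM and IVL at 672 ± 311 against 424 ± 182. SNAI2, CXCL1 and CXCL8 had log2 fold changes of -0.22, -0.68 and -0.42 (adjusted p = 0.698, 0.667 and 0.671).

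Interferon response genes were lower in 501mel than in 1341D CM in 30 of 32 cases, with a median of -0.68 (adjusted p = 2.8e-07; adjusted p = 0.794 with an estimated correlation). The medians by pair were 0.15, -1.41 and -0.54, so pair 1 went the other way. The cytosolic RNA sensor DDX58 measured 4.64 ± 2.17 against 11.1 ± 2.62 FPKM and RSAD2, an antiviral enzyme, 7.33 ± 4.14 against 14.5 ± 8.98. Cholesterol synthesis genes had 20 of 22 lower (median -0.32, adjusted p = 4.2e-05; adjusted p = 0.794 with an estimated correlation), as in SC5D, an enzyme of the pathway, at 21 ± 1.55 against 35.0 ± 12.4 FPKM and STARD4 at 6.63 ± 2.86 against 10.7 ± 0.51. Desmosome genes were lower in 15 of 17 cases (median -0.12, adjusted p = 0.00311; adjusted p = 0.794 with an estimated correlation), DSC1 at 1.70 ± 1.01 against 6.91 ± 5.47. Cell cycle genes had 24 of 29 higher and a median of 0.20 (adjusted p = 3.3e-06; adjusted p = 0.760 with an estimated correlation). UBE2C, an enzyme of mitotic exit, was at 11 ± 6.53 against 6.42 ± 3.21 and cyclin B1 (CCNB1) at 8.57 ± 2.89 against 5.6 ± 1.41. Stress response genes had 17 of 23 lower (median -0.14, adjusted p = 0.0254; adjusted p = 0.794 with an estimated correlation), with the serine synthesis enzyme PSPH at 12.7 ± 8.79 against 19.8 ± 12.8. Melanocytic genes, markers of another cell type, were lower in 17 of 21 cases (median -0.19, adjusted p = 0.00227; adjusted p = 0.794 with an estimated correlation). The pigment enzyme DCT was at 4.57 ± 1.13 against 7.30 ± 1.75 FPKM and the melanosome protein PMEL at 18 ± 2.20 against 23.7 ± 3.42. The 13 mitochondrially encoded genes were higher (median 0.15, adjusted p = 0.0348; adjusted p = 0.794 with an estimated correlation).

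Pair 1 was also opposite for cholesterol synthesis (0.05, -0.64 and -0.43), desmosome (0.11, -0.26 and -0.32) and mitochondrially encoded genes (-0.08, 0.20 and 0.31), and pair 2 for stress response genes (-0.43, 0.19 and -0.18). No gene passed the limma test here. Of all genes, 1067 had an unadjusted p under 0.05 (751 by chance), voom called 0 and 95 met the authors' threshold, 60 higher and 35 lower. With replicates 1 and 2 alone 24 were higher and 22 lower, with 1 and 3 alone 53 and 54, and with 2 and 3 alone 281 and 116. Adjusted over the list alone, 3 differentiation genes (2 lower), 1 wound keratin and 1 protease gene passed. Without 501mel CM replicate 1, 81 genes were called and DSG1 passed (-1.74, adjusted p = 0.0457). With replicates 2 and 3 alone, which may not be independent, 182 were called and DSG1 passed (-1.87, adjusted p = 0.0133). Without 501mel CM replicate 2 the interferon and desmosome calls ended (adjusted p = 0.0540 each, interferon median -0.19), without its replicate 3 the desmosome call (0.0942) and without its replicate 1 the melanocytic call (0.0868). With 1 library left out, list medians ran from -1.14 to -0.19 for interferon, -0.62 to -0.19 for cholesterol synthesis, -0.26 to -0.09 for desmosome, 0.17 to 0.30 for cell cycle, -0.29 to -0.03 for stress response, -0.22 to -0.11 for melanocytic and 0.07 to 0.25 for mitochondrially encoded genes. The stress response call ended without 501mel CM replicate 1 or 3 (adjusted p = 0.966 and 0.162) or 1341D CM replicate 1 (0.840). The mitochondrial call ended without 501mel CM replicate 2 or 3 (0.177 and 0.523) or 1341D CM replicate 2 or 3 (0.210 and 0.0985). The 16 lists not called had adjusted p from 0.0517 to 0.982. Median, mean and test differed in sign for the differentiation, epithelial-mesenchymal transition, Notch and fibroblast lists.

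The remaining comparisons ask what CM of keratinocytes with less desmoglein 1 does to melanoma cells. The keratinocytes that made the media were not sequenced, so the knockdown is not visible in these data, and DSG1 in the melanoma cells was near 0 (0.00549 FPKM in shDsg1 and 0.00291 in shNT CM for WM1341D, listed at 0 for 501mel) and was not tested. In WM1341D cells the chemokine CXCL1 measured 38.1 ± 13.4 FPKM (SD, n = 3) in shDsg1 CM and 38.5 ± 12.7 in shNT CM, a log2 fold change of -0.03 with a 95% interval of -0.18 to 0.12. CXCL8 had 13.4 ± 2.07 against 11.5 ± 1.32 FPKM (log2 fold change 0.19, interval -0.07 to 0.45) and SNAI2 22 ± 6.80 against 22.7 ± 7.36 (-0.04, -0.20 to 0.12). The highest statistics were those of RILP, an effector of late endosome transport (4.16 ± 0.35 against 3.07 ± 0.27), C1QL4 (11.8 ± 3.16 against 9.69 ± 2.61) and TNFRSF12A, the receptor of the cytokine TWEAK (20.8 ± 3.32 against 16.4 ± 4.32). The lowest were those of KLHL24 (2.92 ± 0.92 against 3.65 ± 1.01), SMIM1 (4.10 ± 0.95 against 4.98 ± 1.17) and the histone gene HIST1H1C (1.32 ± 0.44 against 2.03 ± 0.78).

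Interferon response genes had higher values in shDsg1 CM in 21 of 24 cases, with a median of 0.20 (adjusted p = 6.5e-10; adjusted p = 0.545 with an estimated correlation) and medians by pair of 0.18, -0.04 and 0.47. IFI6 measured 255 ± 180 against 134 ± 57.4 FPKM, ISG15, a ubiquitin-like modifier, 30.1 ± 26.3 against 14.3 ± 6.44 and IFI35 45.5 ± 5.55 against 38.6 ± 2.74; adjusted over the list alone 1 gene passed. Cell cycle genes had 25 of 30 higher, a median of 0.08 and medians by pair of 0.19, -0.02 and 0.05 (adjusted p = 0.000158; adjusted p = 0.545 with an estimated correlation), as in E2F1, a factor of S phase entry, at 53.2 ± 6.47 against 49.1 ± 5.17. Melanocytic genes were lower in 18 of 22 cases (median -0.10, adjusted p = 0.000252; adjusted p = 0.545 with an estimated correlation). TRPM1, an ion channel gene driven by MITF, had 1.26 ± 0.40 against 2.12 ± 0.68 FPKM, tyrosinase (TYR) 7.20 ± 2.29 against 9.90 ± 3.37 and GPR143, a receptor of melanosomes, 2.73 ± 0.28 against 4.47 ± 2.20. Their differences by pair were -0.19, -0.08 and -1.11 for TRPM1, -0.03, -0.06 and -1.09 for TYR and -0.36, -0.02 and -1.08 for GPR143, so most of each lay in pair 3. The shNT replicate 3 library held transcripts of 501mel cells, at a median of 4.97% of their 501mel level over 17 genes chosen for over 50 FPKM in 501mel cells and under 2% of that, on average, in the other 5 WM1341D libraries. With genes chosen in the same way without each of those 5 in turn (15 to 16 genes), its median was 0.0576% or less. The 17 genes include MLANA, SLC45A2 and KIT of this list and FSCN1 (1.31 ± 0.51 against 4.61 ± 5.20 FPKM) of the migration list. Genes of the invasive melanoma state had 10 of 12 higher and a median of 0.06 (adjusted p = 0.00912; adjusted p = 0.545 with an estimated correlation), FOSL1, a factor of the AP-1 family, at 40.3 ± 14.5 against 30.9 ± 11.4. Mitochondrially encoded genes were all lower (median -0.18, adjusted p = 0.000482; adjusted p = 0.545 with an estimated correlation), at -0.59, -0.09 and 0.15 by pair.

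No gene passed the limma test. Of all genes, 506 of 13798 had an unadjusted p under 0.05 where 690 would by chance, voom called 0, and 10 met the authors' threshold, 3 higher and 7 lower. Without replicate 3 of shDsg1 or of shNT, the calls of interferon (adjusted p = 0.131 and 0.115), melanocytic (0.165 and 0.166) and invasive genes (0.283 each) ended. Without either replicate 1 the cell cycle call ended (adjusted p = 0.569 each) and mitochondrially encoded genes turned to a median of 0.02 (adjusted p = 0.515). With 1 library left out, list medians ran from 0.08 to 0.26 for interferon, 0.01 to 0.13 for cell cycle, -0.12 to -0.03 for melanocytic and 0.03 to 0.11 for invasive genes. Lists not called had medians from -0.06 to 0.09 (adjusted p = 0.0598 to 0.849). Median, mean and test differed in sign for the desmosome, TGF-beta and protease lists.

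**Figure D4:**
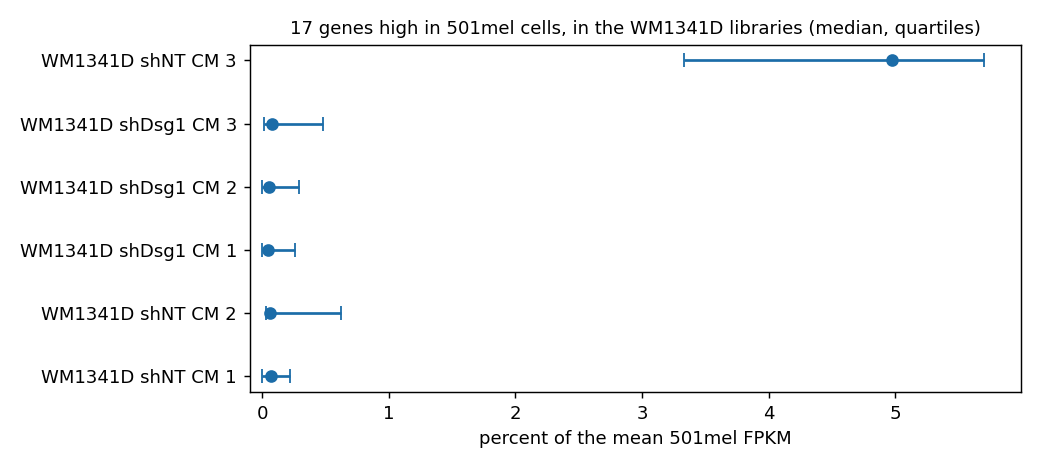
Level in each WM1341D library of 17 genes chosen for over 50 FPKM in 501mel cells and under 2% of that, on average, in the WM1341D libraries other than shNT replicate 3, as a percentage of the mean 501mel FPKM (point, median; bar, quartiles; 1 row of the axis per library). The shNT replicate 3 library lies at 4.97% (3.33 to 5.70) and the medians of the other 5 libraries, which the choice of genes keeps low, at 0.0799% or less.

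In 501mel cells the same comparison showed small differences. BLVRB, a reductase of biliverdin, measured 33.6 ± 3.80 FPKM (SD, n = 3) in shDsg1 CM and 41.2 ± 4.45 in shNT CM, a log2 fold change of -0.29 (SE 0.04, adjusted p = 0.538). GPR89B, which has a near-identical neighbour on the chromosome with which reads may be shared, had 1.05 ± 0.12 against 2.64 ± 0.55 FPKM (log2 fold change -0.82, adjusted p = 0.632) and RABAC1 4.35 ± 0.64 against 5.66 ± 0.55. The highest statistics were those of METAP1D, a mitochondrial aminopeptidase (1.84 ± 0.23 against 1.31 ± 0.22), CHPF2 (5.53 ± 0.95 against 4.64 ± 0.97) and AC007325.2, a locus on an unplaced scaffold (2.19 ± 0.94 against 1.28 ± 0.42). NOTCH2 had 9.99 ± 0.89 against 8.86 ± 0.68 FPKM, and BCL2A1, a survival gene driven by MITF, 4.76 ± 0.52 against 6.01 ± 0.38. SNAI2 had 46.1 ± 7.11 against 46.4 ± 11.1 FPKM (interval of the log2 fold change -0.16 to 0.17). CXCL1 was listed at 0 against 0.0231 ± 0.0400 and CXCL8 was at 0.115 ± 0.053 against 0.158 ± 0.115 FPKM.

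None of the 13798 genes passed the limma test, 530 had an unadjusted p under 0.05 (690 by chance), 15 met the authors' threshold (11 higher, 4 lower), and voom called 2, GPR89B and AC233968.1, the second chosen after its values were seen. Leaving out shDsg1 replicate 1 gave 1 call (SSX2), shDsg1 replicate 2 gave 2 (SNORD12B and AC018692.3) and shNT replicate 2 gave 1 (AC018692.3), all chosen after their values were seen. None of the 19 lists tested was called (medians from -0.03 to 0.07, adjusted p = 0.107 to 0.988), and no member passed adjusted over the list alone. Median, mean and test differed in sign for the epithelial-mesenchymal transition, NF-kB and p53 lists. The correlation of the shDsg1 effects in the 2 lines across genes was -0.0360.

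**Figure D5:**
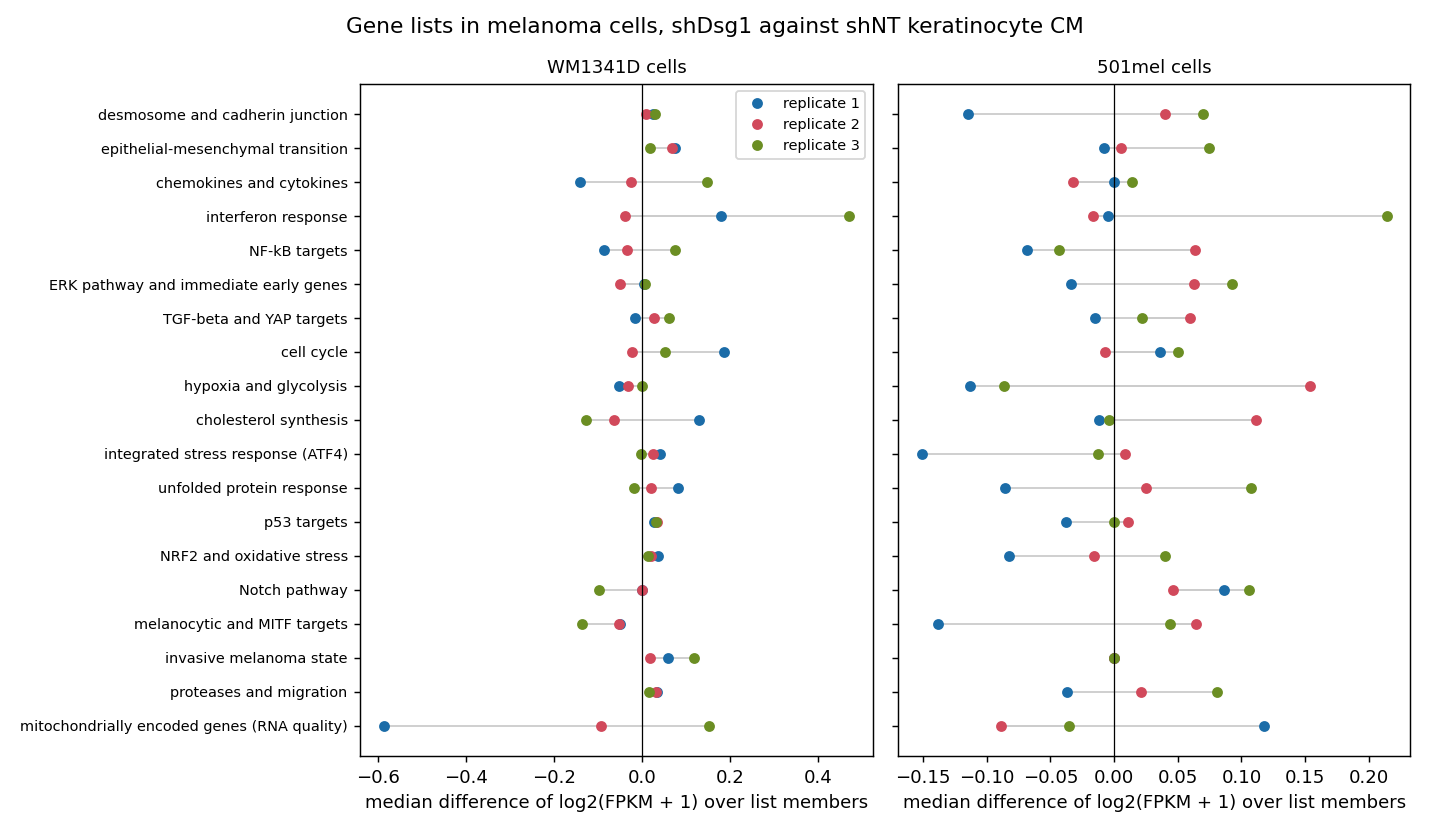
Median difference of log2(FPKM + 1) between shDsg1 and shNT keratinocyte CM over the members of each gene list with at least 5 tested members, in WM1341D (left) and 501mel cells (right), 1 point per same-numbered pair. Interferon response genes lie at 0.18, -0.04 and 0.47 in WM1341D cells for pairs 1, 2 and 3.

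The difference of the shDsg1 effect between the lines (501mel minus WM1341D) was tested directly. The lowest statistics were those of GPR89B (log2 difference -1.21, SE 0.18, adjusted p = 0.852), C1QL4 (-0.40, adjusted p = 0.884) and BLVRB (-0.33, adjusted p = 0.884), and the highest those of KLF2, a transcription factor induced by flow (0.41), C1GALT1C1L (0.60) and AC240274.1 (0.48). Interferon genes had a median difference of -0.14 with 19 of 24 negative (adjusted p = 0.0229; adjusted p = 0.771 with an estimated correlation), IFI35 at -0.23 and IRF7 at -0.40. Stress response genes had a median of -0.04 with 17 of 21 negative (adjusted p = 0.0229; adjusted p = 0.771 with an estimated correlation), ATF5 at -0.25 and CTH, an enzyme of cysteine synthesis, at -0.20. Notch genes had a median of 0.10 with 8 of 11 positive (adjusted p = 0.0278; adjusted p = 0.771 with an estimated correlation), the receptors NOTCH2 and NOTCH3 at 0.19 and 0.32 and the feedback inhibitor NRARP at 0.27. Melanocytic genes had a median of 0.06 with 17 of 22 positive (adjusted p = 0.0380; adjusted p = 0.771 with an estimated correlation), GPR143 at 0.49 and MITF, the master regulator of pigment cells, at 0.12; here too 1 WM1341D library held 501mel transcripts. SNAI2, CXCL1 and CXCL8 had differences of 0.05, 0.00 and -0.24 (adjusted p = 1 each). In 501mel cells CXCL1 and CXCL8 were near 0 FPKM in both media, so an effect there could not be measured. Their differences therefore speak of the WM1341D cells and do not compare the lines.

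No gene passed the limma test for this difference. Of all genes, 490 had an unadjusted p under 0.05 (690 by chance), voom called GPR89B alone, and 29 met the authors' threshold (17 higher, 12 lower). No list member passed adjusted over the list alone. Without WM1341D replicate 3 of shDsg1 or shNT the interferon median turned to 0.01 and 0.00 (adjusted p = 0.932 and 0.933) and the melanocytic call ended (0.659 and 0.660). The interferon call also ended without either 501mel replicate 1 (0.0969 and 0.0949) or replicate 2 (0.213 each), and the melanocytic call without either 501mel replicate 2 (0.434 each) or 3 (0.390 and 0.383). The stress response call ended without either WM1341D replicate 1 (0.0559 and 0.0554) or 501mel replicate 1 (0.364 and 0.360). The Notch call ended without either WM1341D replicate 3 (0.126 and 0.128) and without any 1 of the 6 501mel libraries (0.0507 to 0.128). With 1 library left out, list medians ran from -0.09 to -0.0094 for stress response, 0.05 to 0.18 for Notch and 0.03 to 0.15 for melanocytic genes. The 15 lists not called had medians from -0.14 to 0.16 (adjusted p = 0.0672 to 0.855). The highest of these lay further from 0 than the median of any called list. Median, mean and test differed in sign for NF-kB targets.

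The last comparison describes the 2 melanoma lines themselves in shNT CM. Of 22 melanocytic genes, 5 were higher and 11 lower in WM1341D than in 501mel cells, with the same counts adjusted over the list alone. Members of this list went both ways. Lower in WM1341D were tyrosinase (TYR) at 9.90 ± 3.37 FPKM (SD, n = 3) against 232 ± 4.39 (log2 fold change -4.47, adjusted p = 1.3e-08), TYRP1 at 137 ± 14.2 against 1079 ± 95.5 (-2.97) and MLANA, the Melan-A antigen, at 2.83 ± 4.62 against 251 ± 32.9 (-6.76), of which WM1341D replicate 3 alone held 8.17. DCT was higher at 694 ± 26.9 against 212 ± 55.0 (1.74), as were BCL2A1 at 123 ± 34.0 against 6.01 ± 0.38 (4.11) and S100B at 99.5 ± 5.27 against 22.6 ± 2.95 (2.10). PMEL (3129 ± 648 against 2159 ± 329, adjusted p = 0.0953), MITF (-0.32, adjusted p = 0.0719) and SOX10 (0.06, adjusted p = 0.764; -0.15 with voom or with plain read totals) did not pass, though MITF passed with a replicate block. Of 12 invasive state genes tested 10 were higher in WM1341D and none lower, the same counts adjusted over the list alone: TGFBI, a matrix protein, stood at 29.8 ± 2.94 against 0.00348 ± 0.00312, THBS1 at 14.6 ± 3.92 against 0.00710 ± 0.00361, FOSL1 at 30.9 ± 11.4 against 0.562 ± 0.318 and ZEB1, a repressor of epithelial genes, at 2.70 ± 0.37 against 0.00314 ± 0.00282. NT5E, SOX2 and SOX9 had 14.0 ± 2.23, 4.11 ± 0.67 and 1.58 ± 0.38 FPKM in WM1341D and were listed at 0 in all 3 501mel libraries. CXCL1 was higher in WM1341D at 38.5 ± 12.7 against 0.0231 ± 0.0400 FPKM (5.22, adjusted p = 1.3e-08) and CXCL8 at 11.5 ± 1.32 against 0.158 ± 0.115 (3.44, adjusted p = 8.7e-10), and SNAI2 was lower at 22.7 ± 7.36 against 46.4 ± 11.1 (-1.02, adjusted p = 0.00648). In all, 4179 genes were higher and 4178 lower, 8357 of 13798, and 1603 and 1536 met the authors' threshold. The even balance belongs to this scaling. With plain read totals 3165 were higher and 5342 lower, with a shift of -0.18 in the median log2 fold change of all genes. With voom, which also scaled by plain read totals, 3849 were higher and 6535 lower, with a shift of -0.29.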

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

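The tests of the mixture and of 501mel transcripts, and the splits of the samples, were chosen only after the results they measure were seen. Gene lists whose shDsg1 effect differed between 501mel and WM1341D cells by a test of the difference were interferon response (adjusted p = 0.0229), integrated stress response (0.0229), Notch pathway (0.0278) and melanocytic genes (0.0380). With an estimated correlation the adjusted p was 0.771 for each, and leaving out 1 library ended each call, as given with that comparison: without 1 of the WM1341D replicate 3 libraries the interferon median was 0.01 and 0.00. Groups of 3 are too small for a test of outlying samples, so none was run.

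In keratinocytes, replicate 3 lay between replicates 1 and 2 for most genes in each medium. A separate culture with its own variation is argued against: the highest median residual of replicate 3 over the 3 media, 0.0885, lies below the lowest of the 12 melanoma cell fits, 0.129. Material of replicates 1 and 2 in replicate 3 is compatible with the data: at least 99.8% of the 4-fold different genes lay between. That choice of genes gave 50% to 81.6% in melanoma cell groups. Sources from the same medium ranked first of 9 in 3 of 3 media, but a separate culture in that medium could give this too. With replicate 1 from another medium the lowest residuals were close: 0.0664 against 0.0591 in 1341D, 0.0999 against 0.0885 in 501mel and 0.0747 against 0.0623 in melanocyte CM. Whether cells, RNA or reads were put together stays open, and so does a separate culture of intermediate state with little variation of its own; no biological explanation was tested.

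Transcripts of 501mel cells were present in WM1341D shNT replicate 3. A switch to pigment genes in those cells is argued against, because the 14 genes outside the melanocytic list stood at a median of 5.02% of their 501mel level and the list genes at 3.55%. Cells, RNA or reads of 501mel in that library are consistent with the median of 4.97% over all 17 genes, with a fitted share of 3.82% of reads; which of them it was stays open.

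Interferon response genes had lower values in keratinocytes in 501mel CM than in melanocyte CM. A different share of replicate 1 in replicate 3 is argued against as the whole cause, since with replicates 1 and 2 alone the list median was -1.11. The melanocyte CM libraries stay open as a cause: the median against 1341D CM, which leaves them out, was -0.68, but 0.15 in pair 1 and -0.19 without 501mel CM replicate 2, which ended the call. A difference between cultures stays open too: pair 1 gave -0.15 and pair 2 -1.95. The call held with each of the 6 libraries left out in turn (medians from -1.53 to -0.74). That cannot decide the question, because replicate 3 was fitted as 57.1% (501mel CM) and 76.7% (melanocyte CM) replicate 2. A biological effect of the medium stays open beside a difference between cultures, untested.

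Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05 in every comparison of 2 groups. For genes called, the real split and the highest of the others gave 0 and 0 for 1341D CM (10 of 10 splits as large), 1 and 0 for 501mel CM (1 of 10), 0 and 0 for the 2 melanoma media (10 of 10), 0 and 71 for WM1341D cells (10 of 10), 0 and 2 for 501mel cells (10 of 10) and 8357 and 0 between the lines (1 of 10). At the authors' threshold they gave 184 and 548 (3 of 10), 508 and 560 (2), 95 and 460 (5), 10 and 89 (8) and 15 and 90 (9), and for lists called 7 and 9 (5), 7 and 13 (2), 7 and 7 (3), 5 and 8 (4) and 0 and 3 (10), in the same order without the lines. Where the real count is 0, every split is bound to be as large, so such a share decides nothing. This holds for genes called in the difference between lines (0 against a highest of 63, 100 of 100 splits). For that difference, 96 of 100 splits had as many genes at the authors' threshold (29 against 209) and 41 of 100 as many lists (4 against 8). A random grouping is therefore not excluded. The 71 genes in WM1341D cells and the 460 between the melanoma media, against a real 0 and 95, came from splits that part 1 of 3 pairs. With a replicate block such a split measures mostly the difference inside that pair, so these counts speak of single pairs and their cause was not tested. The 560 in 501mel CM came from a split that parts all 3. Among the 4 splits that part the numbered pairs as the real one does (21 for the difference), the highest other counts were 0, 0, 0, 1, 0, 1 and 0 genes called and 108, 560, 119, 16, 20, 52 and 21 at the authors' threshold. For lists they were 7, 5, 7, 7, 3 and 7, against a real 7, 7, 7, 5, 0 and 4, so groupings other than the real one gave as many list calls or more in 5 of 6 comparisons.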

How the results depend on the processing

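The alternatives with voom, protein coding genes, every gene kept, plain read totals and replicates taken by pairs were chosen after seeing the data; the cause of a difference was not tested unless given. Genes called in 1341D CM against melanocyte CM numbered 0 to 887 when 1 library was left out, 1 (CA9) among protein coding genes and 633 with replicates 2 and 3 alone. For 501mel CM they numbered 0 to 2528 with 1 library left out. They were 0 with a pseudocount of 0.1, without a filter, with every gene kept, with the 6 compared libraries alone (fewer samples), with replicates 1 and 2 or 1 and 3 alone. They were 3 with voom or protein coding genes and 3404 with replicates 2 and 3 alone. For 501mel against 1341D CM the numbers were 0 to 81 with 1 library left out and 182 with replicates 2 and 3 alone. In WM1341D cells 1 gene (RNA5SP283) was called without the replicate block or with a block common to both lines, and 5 with every gene kept. In 501mel cells 0 to 2 were called with 1 library left out, 2 with voom and 8 with every gene kept. For the difference between lines 1 was called without the block, with a common block or with voom, and 6 with every gene kept. The authors' threshold gave 184, 508, 95, 10, 15, 29 and 3139 genes, and the stricter one 3134 between the lines. Calls shared by both melanoma media went from 0 to 121 at the authors' threshold and 568 with replicates 2 and 3 alone. The 30 list calls went to 0 with an estimated correlation or fry.

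DSG1 in 1341D CM turned to -0.0098 with plain totals, -0.0058 with replicates 1 and 2 and -0.080 with 1 and 3 alone, and ran from -0.13 to 0.50 with 1 library left out. In 501mel CM it ran from -1.65 to -0.98 with 1 library left out and was -1.52 with replicates 2 and 3 alone, and passed at -1.65 and -1.52; its adjusted p ran from 0.00338 to 0.846. CA9 in 501mel CM kept its sign in all 17 alternatives (-4.46 with voom to -2.03 with replicates 1 and 3, adjusted p from 0.00275 to 0.781) and its call in 7. In 1341D CM, SNAI2 turned to -0.025 with voom, -0.023 with plain totals and -0.066 with replicates 1 and 3, with a range of -0.075 to 0.25 with 1 library left out; CXCL8 turned to 0.030 with replicates 1 and 2 and 0.061 with 1 and 3 (-0.24 to 0.11). In 501mel CM, CXCL1 turned to 0.072 with replicates 1 and 3 (-0.51 to 0.13) and SNAI2 to 0.023 with replicates 2 and 3 (-0.30 to 0.027). Ranges with 1 library left out that cross 0 were -0.10 to 0.028 for CXCL1 and -0.11 to 0.00031 for SNAI2 in WM1341D cells, -0.11 to 0.067 for CXCL8 and -0.071 to 0.063 for SNAI2 in 501mel cells, and -0.060 to 0.071 for CXCL1 and -0.029 to 0.12 for SNAI2 in the difference. Between the lines SOX10 ran from -0.029 to 0.16 with 1 library left out and was -0.15 with voom and with plain totals, and SNAI2 missed the threshold with every gene kept (adjusted p = 0.0521). Medians that turned were those of mitochondrially encoded genes in WM1341D cells (-0.36 to 0.023) and of interferon genes in the difference (-0.22 to 0.0093).

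Without the replicate block, the list calls that ended were metallothioneins, mitochondrial and stress response genes in 1341D CM (adjusted p = 0.0841, 0.427 and 0.231), desmosome, ERK and mitochondrial genes in 501mel CM (0.110, 0.0874 and 0.312), mitochondrial and stress response genes between these media (0.649 and 0.710), mitochondrial genes in WM1341D cells (0.374) and Notch and stress response genes in the difference (0.239 and 0.574). Lists that passed only without it were cholesterol synthesis in 1341D CM (0.0476) and NF-kB and p53 targets in 501mel against 1341D CM (0.0344 and 0.0280). A block common to both lines ended the calls of invasive genes in WM1341D cells (0.0932) and of stress response and Notch genes in the difference (0.444 and 0.211), where 3 lists were then called, 1 of them new. With a replicate block between the lines, MITF passed. The block changed no other call of a named gene. The count models planned for count data (edgeR, DESeq2 at both thresholds, TMM against size factors, count filters including 50 counts in 3 libraries) were not run, since the test fixed for a table of FPKM was limma. They could have been tried on the recovered reads, as voom was. There were 2771 alternative values for 168 results, each a named gene in 1 comparison, so a gene can count more than once. Of these values 36, in 12 results, turned in sign, 129 newly passed and 11 no longer passed. Genes below the 0.5 FPKM filter were not tested in the reported fits.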

Other observations

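Transcripts of pigment cells were measured in all 3 groups of keratinocyte libraries: PMEL stood at 18.1 ± 6.63, 23.7 ± 3.42 and 18 ± 2.20 FPKM (SD, n = 3) in melanocyte, 1341D and 501mel CM, TYRP1 at 26.7 ± 7.57, 37.5 ± 3.78 and 31.1 ± 1.70, and DCT at 5.61 ± 1.98, 7.30 ± 1.75 and 4.57 ± 1.13. MLANA, chosen after its values were seen, moved with the replicate number. It had 8.99 to 10.1 FPKM in replicate 1, 3.34 to 4.24 in replicate 2 and 4.94 to 5.83 in replicate 3. PMEL, TYRP1 and DCT had smaller SDs relative to their means. The source of these transcripts was not tested. The fibroblast list had 8 tested members in keratinocytes, of which 4 were higher in each melanoma medium than in melanocyte CM (adjusted p = 0.953 and 0.699); the list median by library was 1.04 to 1.26 FPKM in replicate 1, 0.0769 to 0.140 in replicate 2 and 0.283 to 0.619 in replicate 3. Of the leukocyte and endothelial markers 3 were tested in keratinocytes and 1 in melanoma cells, too few for a test. Keratinocyte markers in melanoma cells had 1 tested member of 18. In WM1341D cells the Notch list had 9 of 11 members lower in shDsg1 CM (adjusted p = 0.175) and in 501mel cells 9 of 11 higher (adjusted p = 0.107).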
